A study of Mus musculus with 8 samples.

How the data were processed

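Sections of mouse uterus at postnatal days 3, 8, 12 and 21 (2 per age) were fixed in formalin, embedded in paraffin and read with the Xenium In Situ platform of 10x Genomics, per the labels' protocols. The deposited count matrices hold the number of decoded transcripts per segmented cell and panel feature, whole numbers that the authors did not normalize, per the file headers. The panel has 480 genes, 20 negative control probes and 41 negative control codewords. Cells were outlined by expansion of the nucleus by 5 µm, per the segmentation column of the deposited cell tables, and the software and its version are not given in the sources used here. The cell tables give transcript counts, areas and positions for all 8 sections. The tables print no unit for areas and positions, and micrometres were taken from the platform's format. Count matrices were used for the 4 sections of days 3 and 8, where the sum per cell equalled the count in the cell table in every cell, and those of days 12 and 21 were not used here.

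Control features were left out of all gene sums. Cells with at least 20 gene transcripts were kept (701121 of 701406). Cells were classed by clustering with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2 in Python 3.11.15. Counts were scaled to the median of 344 transcripts per cell and log-transformed, and 20000 cells per section (80000 cells) were reduced to 30 principal components. A graph of 15 neighbours was cut by the Leiden method at resolution 1 into 19 clusters, and the remaining cells were assigned to these. The 11 panel genes of the cell-cycle list and further genes that follow the cell cycle, 15 in all, were left out of the clustering. No doublet caller was run, and transcripts can fall in the outline of a neighbouring cell.

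Clusters were named from marker lists fixed before the data were examined. A cluster was named for a class if at least 3 of its markers were raised 1.5-fold, their median level was at least 0.25 of that in the highest cluster, at least 1 was among its 15 leading genes, no other class had more markers among its 10 leading genes, and no second class that met these limits came within 1 marker of it. The clustering was first run with the cell-cycle genes and then without them, a version of the naming rule that merged smooth muscle and pericyte markers was tried and dropped, and these limits were set after the leading genes of the clusters, but before any test of genes, had been seen. Clusters 0 and 13 were epithelial-like, 1, 2, 9, 10, 11, 12 and 17 stromal fibroblast-like, 5 and 6 smooth muscle-like, 4, 7 and 14 blood endothelial-like and 16 mesothelial-like. Cluster 3 stayed unnamed because pericytes and smooth muscle came within 1 marker of each other (3 and 2 markers among its 10 leading genes). Cluster 18 stayed unnamed because blood endothelial markers (Tie1 and Kdr) came within 1 of the 3 lymphatic markers among its 10 leading genes. Cluster 8 stayed unnamed because its stromal markers lay under the level limit that the similar cluster 10 passed, and cluster 15 because of too few markers. Cluster 8 held 2.34% of cells at day 3 and 7.20% at day 8. The macrophage class has 2 markers on the panel, so that its planned comparison could not be made.

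Tissue pieces were found by linking cells within 12 µm of each other that had at least 8 such neighbours, and groups of at least 10000 cells were kept, 5 per section. Pieces were matched between the 2 sections of an age by position. Overlap of section outlines was measured on a grid of 40 µm as the best over shifts and rotations of up to 24 degrees. Each was tried upright and upside down, with and without a mirror flip. Distances were taken between cell centroids. Epithelial-like cells were linked within 15 µm, and a group of 3 to 60 cells was called small and one of over 100 large. Stromal fibroblast-like cells within 30 µm of an epithelial-like cell were called near, and those over 60 and up to 150 µm away far.

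Transcripts were summed per section, or per section and class, zone or kind of group, since cells are not replicates. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons within a section had the section as a term. CPM are transcripts relative to all gene transcripts of a sum, scaled by TMM (control probes unscaled), given as mean ± SD over 2 sections, and log2 fold changes are given ± SE. A gene counted as a class's own if its CPM there was at least 0.25 of that in the class where it is highest. Lists of cell-cycle genes, steroid receptors and their targets, gland and secretory genes, Hedgehog, Notch, BMP and TGF-beta genes, growth factors (FGF, IGF and HGF genes, and others such as Pdgfc), contractile genes and angiogenesis genes were described, out of 13 lists with at least 3 members on the panel that were tested per class. They were tested with fry from limma 3.58.1, whose directional test asks whether a list's genes move on balance one way, and with camera, which compares the list with other genes. Shares, distances and cell measures were tested with exact permutation tests, two-sided, with sections as the units. Correlations with age are Pearson's and Spearman's over 8 sections, with Benjamini-Hochberg adjustment over 7 measures, taken over cells with at least 1 gene transcript.

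Genes were named by a rule fixed before the data were examined: among genes past the threshold whose day 8 sections both lay on the same side of both day 3 sections, and for classes among the class's own genes, the 8 with the largest rise and the 8 with the largest fall. Up to 4 genes with the smallest p of each described list, and Esr1, Pgr, Foxa2 and Mki67, were added. Genes with under 50 CPM at day 3 were taken to lie near the background. Some genes that the rule picks are not reported here.

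The test was tested on simulated data, counts drawn from the real means and library sizes, with 200 of 480 genes changed. For the whole-section comparison, for epithelial-like and for stromal fibroblast-like cells, it recovered 100 of 100 genes at a log2 fold change of 1 and 100 of 100 at 0.5, and called 13, 5 and 4 of 280 unchanged genes. The simulation used a single fixed dispersion for every gene, not the spread seen between the 2 sections of an age. Its recovery and false calls therefore do not show how the test performs at that spread, or at the spread between animals. The total of 49511958 to 84666919 transcripts per section leaves little counting error in abundant genes, while 10 CPM in a class with few cells rests on few transcripts.

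Alternatives fixed before the data were examined were the size factors and Wald test of DESeq2 1.42.0, total counts as the scale, no filter on low counts, a test against a 1.5-fold change, other minimum transcripts per cell, other cluster resolutions, classes by marker score, cells with neighbours of their own class only, other zone and group limits, the replicate number as a block, and each replicate left out. Alternatives chosen after the data were examined were 1 mean per age for the cell measures, tissue pieces as replicates or blocks, pieces 1 and 2 of day 3 and pieces 1 and 4 of day 8 left out, single clusters added or left out, and genes under 50 CPM left out.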

Results

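Transcripts of 480 genes were read in place, with the Xenium platform, in formalin-fixed, paraffin-embedded sections of mouse uterus at postnatal days 3, 8, 12 and 21, with 2 sections per age. The series is about how the uterus develops after birth, and age is its only stated factor. The day 3 sections held 139806 and 125554 segmented cells with 54347953 and 49511958 gene transcripts in cells, and the day 8 sections held 214768 and 221278 cells with 81461508 and 84666919. The day 12 sections held 389349 and 367168 cells and the day 21 sections held 462894 and 541215 cells. The median was 351 and 357 transcripts per cell at day 3, 336 and 340 at day 8, 331 and 330 at day 12, and 310 and 285 at day 21. Expression was compared between days 3 and 8, and the cell tables of all 8 sections were compared across the ages. The count matrices of days 12 and 21 are not analysed here.

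The outlines of the 2 sections of an age overlapped by 75.4 to 86.1% after alignment (4 pairs), against 19.1 to 45.4% for sections of different ages (24 pairs). Each day 3 and day 8 section held 5 large tissue pieces, and a piece of the first section could be matched to a piece of the second. Gene totals of the 2 sections of an age correlated over the 480 genes, which are not independent replicates, at r = 0.9996 (day 3) and r = 0.9998 (day 8), and yet they differed beyond sampling noise (chi-square 35956 and 42804 on 479 degrees of freedom). The adjusted p-values over sections below therefore measure the spread between sections of overlapping tissue, and they are too small for a statement about animals. Whether pieces or sections come from different animals is not given in the sources used here. Each count over all genes and each gene list is therefore also given with the 5 pieces of each age as replicates, a setting chosen after the data were examined.

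Epithelial-like cells made up 20.96% ± 0.318 of the cells at day 3 and 18.2% ± 1.35 at day 8 (mean ± SD, n = 2 sections), and stromal fibroblast-like cells 47.2% ± 0.612 and 31.7% ± 0.586. Smooth muscle-like cells made up 11.7% ± 0.462 at day 3 and 8.24% ± 0.267 at day 8, and blood endothelial-like cells 11.02% ± 0.333 and 15.05% ± 0.130. Mesothelial-like cells made up 1.02% ± 0.0345 and 1.15% ± 0.0593. Cluster 3, whose leading genes include the smooth muscle gene Myh11 and the pericyte genes Kcnj8 and Abcc9, held 5.22% ± 0.333 of the cells at day 3 and 16.4% ± 0.143 at day 8. Cluster 8, led by the matrix genes Ltbp2, Thbs2 and Smoc2, held 2.34% ± 0.0956 and 7.20% ± 0.103. Cluster 15, with the macrophage genes Adgre1 and Csf1r, held 0.471% ± 0.00319 and 1.66% ± 0.0200, and cluster 18, with the lymphatic genes Lyve1, Mmrn1 and Flt4, held 0.106% ± 0.0256 and 0.405% ± 0.0403. In each of these 9 classes and clusters the sections of the 2 ages did not overlap, but with 2 against 2 the two-sided exact permutation test cannot go below p = 0.333, which is the p of each. The 2 sections of an age hold matched pieces, and over pieces the epithelial-like and stromal fibroblast-like shares of the 2 ages did overlap. Piece 2 held 25791 epithelial-like cells at day 3 and 39390 at day 8, against 5684 to 9095 and 3963 to 18829 in the other pieces. Some genes that lead these clusters, Myom1 in cluster 3 among them, themselves differed between the ages, so that the shares depend on how cells were classed. With cells classed by marker score, the day 8 share of smooth muscle-like cells was higher by 4.13 percentage points and that of mesothelial-like cells changed by -3.07. With finer clusters the smooth muscle-like share was higher by 0.709. Of the stromal fibroblast-like cells, cluster 10 held 16.0% at day 3 and 1.43% at day 8. The similar cluster 8 was left out of the class, so that part of the lower stromal share at day 8 depends on this split. At day 3, cluster 3 held 12.7% and 7.63% of the cells of pieces 1 and 2 and 1.49%, 0.10% and 1.40% of pieces 3, 4 and 5. At day 8, cluster 15 held 5.31% of the cells of piece 1 and 0.62 to 1.02% of the others.

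**Figure D1:**
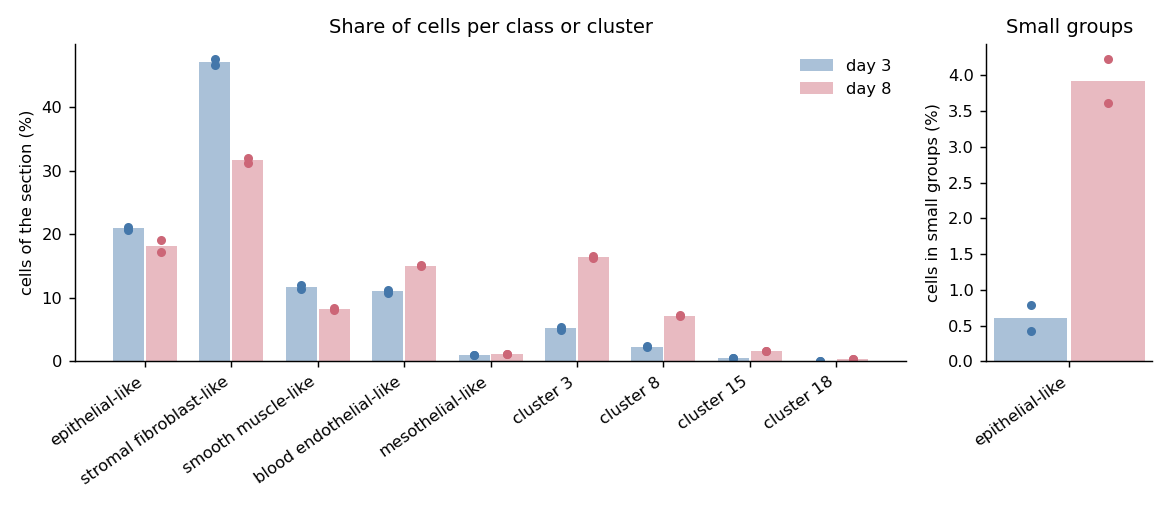
Share of cells (%) per class or cluster in the day 3 and day 8 sections (left), and share of epithelial-like cells (%) that lie in small separate groups (right); points are sections and bars are means of 2. Stromal fibroblast-like cells made up 47.2% of cells at day 3 and 31.7% at day 8, and small groups held 0.612 and 3.92% of epithelial-like cells, each with an exact permutation p of 0.333. Part of the stromal difference depends on cluster 10 being counted as stromal and the similar cluster 8 not.

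The distance from cells of the wall to the nearest epithelial-like cell was taken as a measure of how the layers lie around the epithelium. It also depends on small separate epithelial groups, of which there were 11 ± 4.24 per section at day 3 and 79 ± 1.41 at day 8. How far these groups account for the differences was not tested. The median distance was 52.3 µm ± 3.12 for stromal fibroblast-like cells at day 3 and 45.2 µm ± 0.423 at day 8 (mean ± SD, n = 2 sections). It was 96.1 µm ± 5.47 and 62.0 µm ± 2.46 for smooth muscle-like cells, and 62.8 µm ± 4.599 and 53.0 µm ± 0.0397 for blood endothelial-like cells. The smooth muscle-like class leaves out cluster 3, whose leading genes include Myh11. Mesothelial-like cells lay at 113 µm ± 8.80 and 146 µm ± 8.30. The exact permutation p was 0.333 for each of these 4 classes, the smallest that 2 against 2 allows. Classing cells by marker score turned the direction for 3 of them, to differences of 9.19 µm (stromal fibroblast-like), 19.1 µm (smooth muscle-like) and 5.11 µm (blood endothelial-like). Among the unnamed clusters, cluster 3 lay at 131 and 101 µm and cluster 15 at 69.0 and 62.2 µm (exact permutation p = 0.333 each), cluster 18 at 122 and 152 µm (p = 0.667) and cluster 8 at 144 and 130 µm (p = 1).

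Over the whole section, Gfra3, a co-receptor of the GDNF family, rose from 32.8 ± 0.268 CPM at day 3 to 133 ± 2.09 CPM at day 8 (mean ± SD, n = 2), and Fgf10, a growth factor made by mesenchyme, from 70.8 ± 1.85 to 194 ± 5.08 CPM. Wnt16 rose from 1634 ± 154 to 4470 ± 22.5 CPM and Myom1, a sarcomere protein, from 561 ± 19.4 to 1613 ± 50.2 CPM. The retinoic acid-binding protein Crabp1 fell from 3296 ± 118 to 1147 ± 14.6 CPM, and Amhr2, the receptor of anti-Müllerian hormone, from 93.7 ± 4.23 to 31.6 ± 0.140 CPM. The matrix protease gene Mmp9 and the cytokine gene Il1b were higher at day 8 by log2 fold changes of 2.13 ± 0.06 and 1.66 ± 0.05 (± SE). For Il1b this rests on day 8 piece 1, the piece rich in cluster 15: without it Il1b had a log2 fold change of -0.41, while Mmp9, which leads smooth muscle-like cluster 6 and is among the leading genes of cluster 15, kept 1.504 and passed. Gfra3 and Il1b had under 50 CPM at day 3. All 11 genes of the cell-cycle list fell (11 adjusted over the list alone, 10 over pieces), among them Top2a (log2 fold change -0.69 ± 0.03) and Mki67 (-0.55 ± 0.03), and all 11 were lower under each of the 3 scalings. The list passed fry's directional test (adjusted p = 0.00557). By camera, a comparison with other genes was not passed with an estimated correlation (adjusted p = 0.784) and was passed with a preset one (adjusted p = 0.0000827). With any 1 of the 4 sections left out the fry call was lost (adjusted p = 0.0599 to 0.102), as were those of the other 11 lists called, while with the replicate number as a block it stayed (0.0160). Esr1, the estrogen receptor, rose by a log2 fold change of 0.15 ± 0.02 and Foxa2, a gland gene, fell by 0.70 ± 0.04 on the log2 scale (over pieces, adjusted p = 0.28 and 0.44), while Pgr, the progesterone receptor, had 0.08 ± 0.05 (adjusted p = 0.170). In all, 376 of 480 genes passed 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 201 higher and 175 lower at day 8. With pieces as replicates 58 passed, with 36 higher and 22 lower, and Gfra3, Fgf10, Wnt16, Myom1, Crabp1 and Amhr2 were among them (adjusted p = 0.00033, 0.0087, 0.013, 0.023, 0.018 and 0.020). Of the genes that the rule picks by size, 5 of the 8 largest rises and 5 of the 8 largest falls passed over pieces. Of these 8 rises 3 had under 50 CPM at day 3, and of the 8 falls 4 had.

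**Figure D2:**
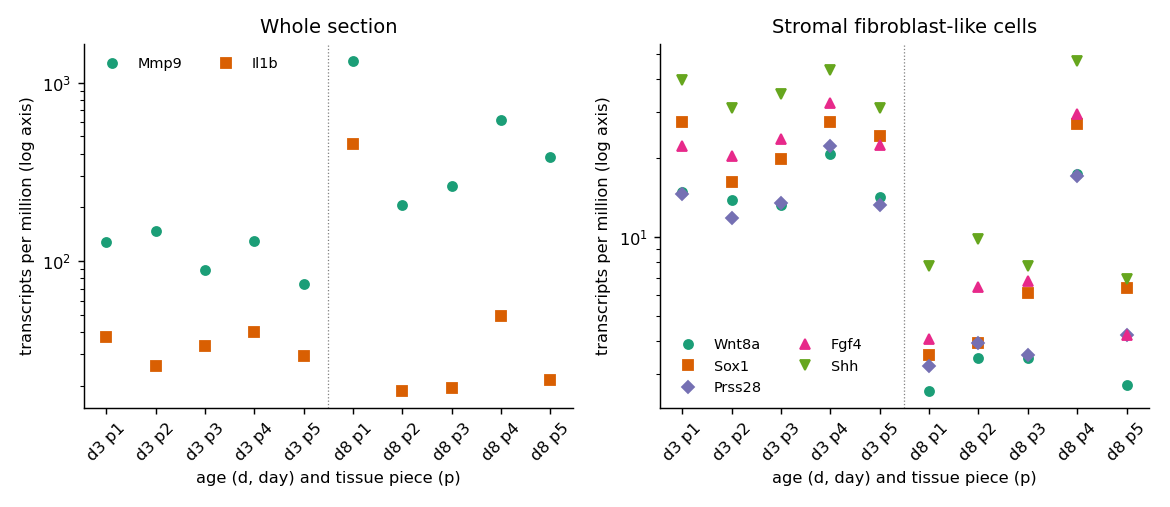
CPM (log axis) in each of the 5 tissue pieces of day 3 (d3) and day 8 (d8), both sections summed: Mmp9 and Il1b over the whole section (left) and 5 rarely read genes in stromal fibroblast-like cells (right). Il1b stands high in day 8 piece 1 only, Mmp9 is above the day 3 pieces in all 5 day 8 pieces, and the 5 rarely read genes in day 8 piece 4 lie with the day 3 pieces.

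In epithelial-like cells, Ihh, a Hedgehog ligand, rose from 26.0 ± 2.26 CPM at day 3 to 85.3 ± 0.0320 CPM at day 8 (mean ± SD, n = 2; log2 fold change 1.72 ± 0.08), against 26.1 and 17.6 CPM in stromal fibroblast-like cells. Cyp26a1, which degrades retinoic acid, rose from 64.9 ± 10.4 to 187 ± 6.06 CPM, and Aldh1a3 and Aldh1a1, which make it, from 927 ± 77.8 to 2362 ± 43.7 and from 2724 ± 353 to 6382 ± 102 CPM. The tight junction gene Cldn10 (1.54 ± 0.05), the glutathione genes Gstm7 (1.24 ± 0.04) and Gpx2 (1.03 ± 0.07) and the WNT inhibitor Wif1 (1.03 ± 0.09) also rose. Gdf15 fell from 282 ± 21.3 to 87.0 ± 0.326 CPM, the cytokine gene Lif from 131 ± 4.31 to 55.1 ± 1.81 CPM, Foxn1 from 44.3 ± 3.00 to 19.0 ± 1.14 CPM and the neurotrophin gene Bdnf from 31.5 ± 0.0254 to 6.56 ± 1.36 CPM. All 8 of the genes named for the largest rises passed over pieces and 6 of the 8 named for the largest falls did. Fgf4 and Shh did not (adjusted p = 0.0846 and 0.0600), and these 2 with Wnt10a, Prss28, Foxn1 and Bdnf had under 50 CPM at day 3, as had Ihh and Wif1 among the rises. Over the same 10 pieces, 133 of 480 genes passed, with 82 higher and 51 lower, against 363 over sections by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 191 higher and 172 lower. Of the 363, 94 of the higher and 114 of the lower genes were the class's own, at no less than 0.25 of the level of the class where they are highest.

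Among the lists, 9 of 11 cell-cycle genes fell in epithelial-like cells and 0 rose (9 adjusted over the list alone, 5 over pieces), among them Ccnd1 (-0.38 ± 0.03), Top2a (-0.38 ± 0.03) and Mki67 (-0.16 ± 0.03), with Mcm5 at 0.11 and Mcm2 at -0.05 not past the threshold, and 10 of 11 were lower under each of the 3 scalings. fry gave an adjusted p of 0.0245 (0.0625 to 0.255 with a section left out), and camera an adjusted p of 0.985 with an estimated correlation and 0.0563 with a preset one. With any 1 section left out, fry called 0 of 13 lists in this class. Of 15 steroid receptors and their targets, 8 rose and 4 fell (12 adjusted over the list alone, 6 up and 2 down over pieces; fry adjusted p = 0.0327, camera adjusted p = 0.985 with an estimated correlation). Those that rose include Esr1, from 2780 ± 31.3 to 4543 ± 10.7 CPM, and the calcium-binding protein gene Calb1, from 5768 ± 276 to 9758 ± 41.8 CPM; Pgr had 17034 ± 255 and 17252 ± 455 CPM (adjusted p = 0.640, edgeR). Over pieces, Esr1 passed (adjusted p = 0.013) and Calb1 did not (adjusted p = 0.052). Of 19 genes of gland and secretory epithelium, 9 rose and 7 fell (16 adjusted over the list alone, 3 up and 3 down over pieces), and fry's directional test was not passed (adjusted p = 0.0567; mixed adjusted p = 0.00421). Axin2 (0.52 ± 0.04), a WNT target, and Prom1 (0.46 ± 0.03) rose, Lif fell, and Foxa2 went from 23.1 ± 0.758 to 29.4 ± 0.496 CPM (log2 fold change 0.35 ± 0.09; over pieces, adjusted p = 0.11), against 25.5 and 10.99 CPM in stromal fibroblast-like cells. With cells classed by marker score the log2 fold change of Foxa2 was -0.36.

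**Figure D3:**
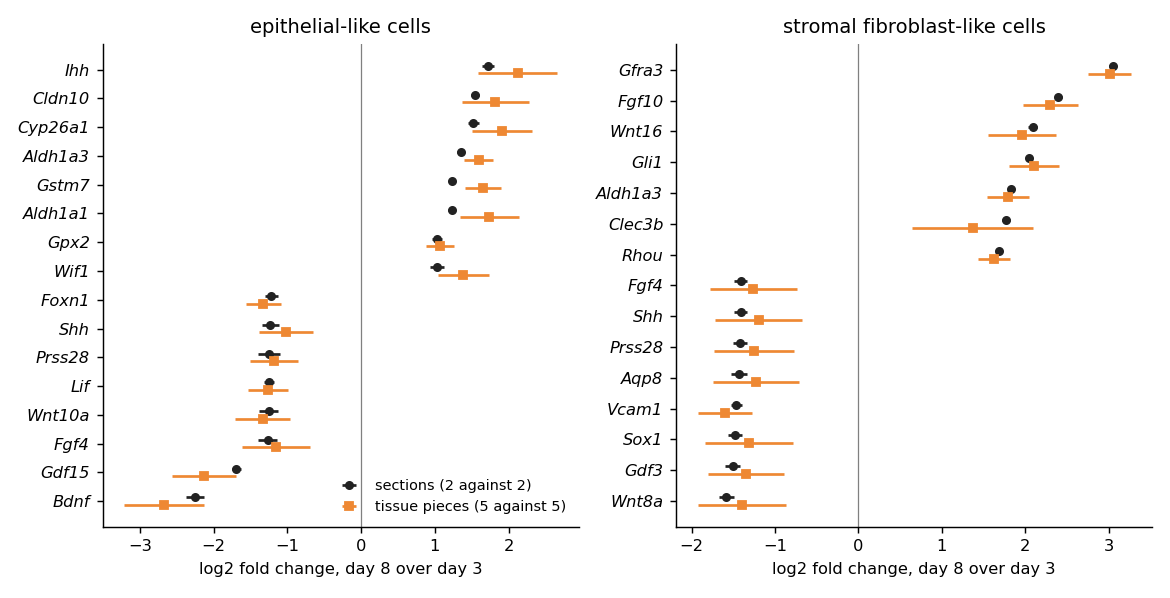
Log2 fold change, day 8 over day 3, of the genes named for the largest rises and falls in epithelial-like (left) and stromal fibroblast-like cells (right), over 2 against 2 sections (circles) and over 5 against 5 tissue pieces (squares), with bars of 1 SE. The 15 rises and 16 falls shown keep their sign over pieces, with wider errors.

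In stromal fibroblast-like cells, Gfra3 rose from 43.7 ± 1.28 CPM at day 3 to 362 ± 3.92 CPM at day 8 (mean ± SD, n = 2; log2 fold change 3.05 ± 0.04), Fgf10 from 97.3 ± 6.69 to 513 ± 4.10 CPM and Wnt16 from 2527 ± 251 to 10741 ± 13.98 CPM. Gli1, the transcription factor that Hedgehog signalling induces, rose from 444 ± 7.12 to 1835 ± 0.561 CPM, and the Hedgehog receptor gene Ptch1 from 321 ± 0.777 to 638 ± 22.6 CPM. Aldh1a3 (1.83 ± 0.03), Rhou (1.69 ± 0.03), a small GTPase, and Clec3b (1.77 ± 0.05) rose too. All of these but Clec3b (adjusted p = 0.15) passed over pieces. Gfra3 had under 50 CPM at day 3. The adhesion gene Vcam1 fell from 94.9 ± 8.26 to 34.3 ± 0.621 CPM. The other 7 genes named for the largest falls, Wnt8a, Gdf3, Sox1, Aqp8, Prss28, Shh and Fgf4, had under 50 CPM at day 3, and over pieces only Vcam1 and Gdf3 of the 8 passed. Over the 77 genes of this class that fell and had under 50 CPM at day 3, the median level relative to the day 3 mean was 1.20 in day 8 piece 4 and 0.337 to 0.413 in the other 4 day 8 pieces. Over sections, 415 of 480 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 213 higher and 202 lower, of which 162 and 118 were the class's own. Over pieces 146 passed, with 86 higher and 60 lower. Different clusters held most of this class at the 2 ages, with clusters 2, 10 and 11 mostly from day 3 and clusters 1 and 9 mostly from day 8; Wnt16, Gfra3, Fgf10 and Gli1 are among the genes that lead cluster 1.

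All 11 genes of the cell-cycle list fell in stromal fibroblast-like cells (11 adjusted over the list alone, 10 over pieces; fry adjusted p = 0.0013, camera adjusted p = 0.802 with an estimated correlation and 0.00000125 with a preset one). Kif11, a mitotic motor, fell from 3092 ± 24.1 to 1508 ± 14.4 CPM, Top2a from 4982 ± 30.6 to 2474 ± 43.6 CPM and Mki67 from 7338 ± 121 to 3877 ± 77.3 CPM, and each passed over pieces. Of 10 Hedgehog genes 6 rose and 3 fell (9 adjusted over the list alone, 3 up and 0 down over pieces; fry adjusted p = 0.0013, camera adjusted p = 0.802 with an estimated correlation); those that fell are the ligands Shh, Dhh and Ihh, at 36.8, 36.9 and 26.1 CPM at day 3. Of 14 genes of the growth factor list 7 rose and 5 fell (12 adjusted over the list alone, 3 up and 2 down over pieces; fry adjusted p = 0.00457, camera adjusted p = 0.802 with an estimated correlation). Hgf rose from 452 ± 3.64 to 1170 ± 12.9 CPM, while Pdgfc fell from 2297 ± 46.0 to 1208 ± 6.98 CPM. With each of the 4 sections left out in turn, fry called the cell-cycle list 4 times and the Hedgehog and growth factor lists 2 times each. Esr1 rose from 12409 ± 140 to 16646 ± 185 CPM and Pgr from 2092 ± 74.8 to 3143 ± 53.5 CPM (over pieces, adjusted p = 0.017 and 0.058), and Pgr was not among the class's own genes. Foxa2 had a log2 fold change of -1.21 ± 0.08 (over pieces, adjusted p = 0.11).

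In smooth muscle-like cells, Gdnf, a growth factor for neurons, rose from 98.2 ± 7.02 to 560 ± 13.8 CPM (mean ± SD, n = 2; log2 fold change 2.51 ± 0.05) and Gli1 from 294 ± 4.88 to 1271 ± 13.04 CPM. Wnt2 rose from 112 ± 0.0554 to 430 ± 2.43 CPM, Inhba, an activin subunit, from 105 ± 0.0734 to 341 ± 1.11 CPM and the neurotrophin receptor gene Ngfr from 800 ± 3.35 to 2326 ± 35.1 CPM. Crabp1 fell from 1438 ± 25.5 to 204 ± 2.99 CPM, the growth factor gene Igf2 from 14985 ± 528 to 6089 ± 165 CPM, the chemokine gene Cxcl12 from 3757 ± 50.8 to 1550 ± 11.6 CPM and Pgf, of the VEGF family, from 1417 ± 3.15 to 518 ± 33.7 CPM. All 8 genes named for the largest rises and 7 of the 8 for the largest falls passed over pieces. Pgr rose from 1443 ± 33.4 to 2899 ± 29.3 CPM (over pieces, adjusted p = 0.0069), but was not among the class's own genes; Esr1 had a log2 fold change of 0.16 ± 0.02. All 3 contractile genes rose (3 adjusted over the list alone, 1 over pieces; fry adjusted p = 0.0158, camera adjusted p = 0.864 with an estimated correlation): Myh11, smooth muscle myosin, from 19727 ± 176 to 32202 ± 324 CPM, with smaller changes in Tagln (0.10 ± 0.02) and Acta2 (0.06 ± 0.03). With total counts as the scale 1 of the 3 was lower. These 3 genes are also among the 4 panel markers that named the smooth muscle-like clusters, and cluster 3, led by Myom1 and Myh11, was left out. The contractile result is therefore not independent of how the class was formed. All 11 genes of the cell-cycle list fell (11 adjusted over the list alone, 7 over pieces; fry adjusted p = 0.00603, camera adjusted p = 0.864 with an estimated correlation and 0.0000440 with a preset one). Hedgehog genes rose in 5 and fell in 5 of 10 (10 adjusted over the list alone, 4 up and 0 down over pieces; fry adjusted p = 0.00217, camera adjusted p = 0.864 with an estimated correlation), Gli1, Ptch1 and Gli2 upward. Of 17 genes of the BMP and TGF-beta list 9 rose and 7 fell (16 adjusted over the list alone, 7 up and 1 down over pieces; fry adjusted p = 0.00271, camera adjusted p = 0.864 with an estimated correlation). With each section left out in turn, fry called the Hedgehog list and the BMP and TGF-beta list 2 of 4 times, and the contractile and cell-cycle lists 0 times. Of 480 genes, 412 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 213 higher and 199 lower (152 and 122 own genes). Over pieces 123 passed, with 86 higher and 37 lower. Cluster 5 of this class came mostly from day 3 and cluster 6 mostly from day 8, and with cluster 3 added the fall of Hoxa13 (-1.78) became 0.017. Gdnf and Wnt2 are among the genes that lead cluster 6, and Pgf is among those that lead cluster 5.

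In blood endothelial-like cells, Selp, an adhesion receptor of activated endothelium, rose from 45.8 ± 5.93 to 107 ± 6.09 CPM (mean ± SD, n = 2; log2 fold change 1.21 ± 0.10), Rgs4 from 300 ± 15.9 to 686 ± 7.55 CPM and Cyp26b1, which degrades retinoic acid, from 187 ± 18.9 to 346 ± 4.61 CPM. Rgs4 leads cluster 14 of this class, whose leading genes include the pericyte gene Pdgfrb and which made up 18.95% of the class at day 3 and 28.5% at day 8. Without cluster 14 the log2 fold change of Rgs4 was 1.14, against 1.20 with it. This cannot exclude pericytes as a source of Rgs4, since cluster 7, which stayed in the class, is led by Olfr78, Hey2 and Heyl. With finer clusters, these 3 genes lead an unnamed cluster whose leading genes include the pericyte gene Notch3 and Rgs4. Rgs4 itself leads another finer cluster, of 13166 cells, that was named pericyte-like and has Pdgfrb, Cspg4 and Notch3 among its leading genes. Selp and Gfra3 had under 50 CPM at day 3. Wnt16, Fgf10, Gfra3 and Gli1 were also higher in this class, but these lead in stromal clusters. Wnt16 is also among the leading genes of epithelial-like cluster 13. With finer clusters it leads an unnamed cluster whose leading genes include the endothelial genes Plvap and Emcn. In endothelial cells whose 5 nearest cells are all endothelial, Fgf10 had a log2 fold change of -0.75, Gfra3 -0.079 and Gli1 -0.10. Selp and Nrg2 did not pass there, and Rgs4, Cyp26b1 and Wnt16 still rose. Pgr had a log2 fold change of 0.40 ± 0.04 and Esr1 0.18 ± 0.02, with -0.16 for Esr1 in those cells. The 8 genes named for the largest falls, Wnt8a, Ereg, Areg, Aqp8, Sox1, Amhr2, Prss29 and Gjb1, all had under 50 CPM at day 3, and only Amhr2 passed over pieces (adjusted p = 0.011). All 11 genes of the cell-cycle list fell (11 adjusted over the list alone, 8 over pieces; fry adjusted p = 0.0176, camera adjusted p = 0.932 with an estimated correlation and 0.00000108 with a preset one), Mki67 from 8922 ± 340 to 6020 ± 53.7 CPM and Top2a from 5691 ± 115 to 3583 ± 53.9 CPM. Of 12 Notch genes 5 rose and 2 fell (7 adjusted over the list alone, 2 up and 0 down over pieces; fry adjusted p = 0.0176, camera adjusted p = 0.932 with an estimated correlation), with Hes1, a Notch target, at 0.53 ± 0.02 and the ligand gene Dll4 at 0.30 ± 0.02. With each section left out in turn, fry called the cell-cycle list 2 of 4 times and the Notch list 1 of 4 times. Of 15 genes of angiogenesis 4 rose and 6 fell (10 adjusted over the list alone, 1 up and 0 down over pieces), and fry's directional test was not passed (adjusted p = 0.476), with Vegfc at 0.32 ± 0.03 and Unc5b at -0.36 ± 0.03. Over sections, 359 of 480 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 183 higher and 176 lower (133 and 133 own genes). Over pieces 52 passed, with 31 higher and 21 lower, and over endothelial cells with endothelial neighbours only, 162.

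The other classes are given as counts by the same test. Mesothelial-like cells had 325 of 475 genes past the threshold, with 160 higher and 165 lower, and with total counts as the scale 115 higher and 185 lower. Cluster 3 had 381, cluster 8 had 380, cluster 15 had 255 of 457 and cluster 18 had 77 of 394. With 1 section left out these were 179 to 261 (mesothelial-like), 342 to 363, 347 to 373, 136 to 246 and 45 to 110, and cluster 18 had 39 with the replicate number as a block. Over pieces they were 49 (mesothelial-like), 77, 38, 18 and 14. A macrophage class could not be formed, since 2 of its markers are on the panel, so that no result stands under that name.

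Whether the epithelium and the stroma changed alike with age was tested by the class-by-age term. The change of epithelial-like cells less that of stromal fibroblast-like cells, on the log2 scale, was 2.19 ± 0.10 for Ihh and 2.34 ± 0.12 for Wif1 (± SE), and 2.71 ± 0.13 for Cyp26a1. Ihh and Wif1 had under 50 CPM in both classes at day 3. It was -3.56 ± 0.14 for Gfra3, -2.89 ± 0.14 for Fgf10 and -1.93 ± 0.04 for Rhou, each of which rose in the stroma. The proliferation gene Mki67 fell less in the epithelium (0.67 ± 0.03), and Pgr had -0.66 ± 0.04 and Esr1 0.20 ± 0.03. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the section as a term, 373 of 480 genes passed, with 165 higher and 208 lower in their epithelial change. The split depends on the scale. With total counts as the scale the median over genes moved from -0.04 to 0.15 and the split became 243 higher and 131 lower. Without day 3 pieces 1 and 2 it was 231 and 142. With pieces as blocks 140 passed, with 60 higher and 80 lower.

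Within the stroma, cells near the epithelium (within 30 µm) were compared with cells 60 to 150 µm away. Near cells had more Bmp3 (log2 fold change 1.43 ± 0.03), the adrenomedullin gene Adm (1.35 ± 0.04), Hhip, a Hedgehog inhibitor (1.34 ± 0.07), Nog, a BMP inhibitor (1.24 ± 0.04), Wnt16 (1.15 ± 0.02), the WNT-responsive Lef1 (1.14 ± 0.03), Bmp7 (1.02 ± 0.02) and the retinol transporter Stra6 (0.99 ± 0.02). Far cells had more Dcn, the proteoglycan decorin (-1.99 ± 0.02), Igf1 (-1.94 ± 0.04), Gdnf (-1.89 ± 0.04), the WNT antagonist genes Sfrp4 (-1.82 ± 0.03) and Sfrp1 (-1.31 ± 0.03), Adh1 (-1.72 ± 0.06) and Fgf10 (-1.59 ± 0.03). Pgr was higher near the epithelium (0.47 ± 0.01) and so was Mki67 (0.19 ± 0.02), while Esr1 was lower (-0.10 ± 0.01) and Foxa2 did not pass (-0.31 ± 0.13). Pgr is higher in epithelial-like than in stromal cells, and is not among the stroma's own genes. Bmp3, Adm and Wnt16 are also among the leading genes of epithelial-like cluster 13. Whether transcripts of neighbouring cells within the outlines enter the near-to-far differences was not tested. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the section as a term, 390 of 480 genes passed, with 196 higher near and 194 higher far. With pieces as blocks 324 passed, among them the 15 genes named above for size.

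The near-to-far difference itself differed between the ages for 289 of 480 genes, 118 upward and 171 downward at day 8 relative to day 3. Crabp1 had 4755 and 5059 CPM near and 3473 and 3532 CPM far at day 3, but 976 and 973 CPM near and 2384 and 2314 CPM far at day 8 (difference in log2 fold change -1.76 ± 0.03). Bmp4 (-1.26 ± 0.05), Gdf7 (-1.23 ± 0.05) and the WNT antagonist gene Frzb (-0.97 ± 0.05) moved the same way. Adh1 (1.33 ± 0.13), Hhip (1.04 ± 0.14), Adm (0.95 ± 0.07), Thbs1 (0.94 ± 0.03) and Cxcl12 (0.89 ± 0.04) moved the other way, and Adh1 had -0.16 when far cells were taken from 100 to 200 µm. Mki67 had -0.32 ± 0.04. With pieces as blocks 81 genes passed, with 40 upward and 41 downward.

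Small separate groups of epithelial-like cells (3 to 60 cells) were compared with the large epithelial groups (over 100 cells). There were 11 ± 4.24 small groups per section at day 3 and 79 ± 1.41 at day 8 (mean ± SD, n = 2), and they held 0.612% ± 0.257 and 3.92% ± 0.435 of the epithelial-like cells (exact permutation p = 0.333, the smallest possible). At day 3 pieces 3, 4 and 5 held 0.00% in such groups and pieces 1 and 2 held 0.08% and 1.17%, against 1.29 to 12.3% in the 5 pieces of day 8. At day 8, small groups had more of the gland genes Foxa2 (190 and 225 CPM in the 2 sections, against 21.003 and 21.7 in large groups; log2 fold change 3.28 ± 0.15) and Cxcl15 (91.0 and 73.1 against 12.5 and 9.75 CPM; 2.88 ± 0.18). Wif1 (2.61 ± 0.14), Ihh (1.80 ± 0.10), Bpifb5 (1.61 ± 0.08), Fst, an activin inhibitor (1.28 ± 0.10), Wfdc15b (1.16 ± 0.04) and Gstm7 (0.998 ± 0.04) were higher too. Small groups had less Prap1 (10.5 and 13.6 against 563 and 606 CPM; -5.60 ± 0.18), Dhrs9 (-3.67 ± 0.21), the endocytic receptor gene Lrp2 (-3.45 ± 0.06), the prostaglandin synthase gene Ptgs2 (-3.39 ± 0.08), Wnt7b (-3.36 ± 0.10), Foxn1 (-2.80 ± 0.47), Calb1 (-2.67 ± 0.04) and Wnt11 (-2.44 ± 0.06). Esr1 was higher (0.62 ± 0.04), Mki67 was higher (0.31 ± 0.06) and Pgr was lower (-0.72 ± 0.04). Stromal fibroblast-like cells had more Esr1 and less Pgr than epithelial-like cells at both ages. Whether transcripts of neighbouring stromal cells within the outlines enter these differences was not tested. The small groups of the 2 day 8 sections held 1564 and 1529 cells. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the section as a term, 345 of 480 genes passed, with 169 higher and 176 lower; with pieces as blocks 290 of 478 passed, among them all 16 genes named here for size.

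Across all 4 ages, sections held more cells with age, from 132676 ± 10080 (mean ± SD, n = 2) at day 3 to 501978 ± 55278 at day 21 (Pearson r = 0.968 and Spearman rho = 0.976 over 8 sections, two-sided exact permutation p = 0.000397 and 0.000794, adjusted p = 0.00139 and 0.00278). The median transcripts per cell went from 354 ± 4.24 to 297.5 ± 17.7 (r = -0.949, rho = -0.976, exact permutation p = 0.000397 and 0.000794, adjusted p = 0.00139 and 0.00278). The median cell area went from 34.5 ± 0.287 to 38.1 ± 1.501 µm² (r = 0.841, rho = 0.878, exact permutation p = 0.00952 and 0.0103, adjusted p = 0.0167 and 0.0241). Cell outlines were expanded from the nucleus, so that this area is not that of measured cell borders. Control probe CPM, relative to gene transcripts, went from 43.5 ± 1.35 to 28.7 ± 0.0537 (r = -0.893, rho = -0.781, exact permutation p = 0.00794 and 0.0349, adjusted p = 0.0167 and 0.0454). The nucleus area (r = 0.710, rho = 0.761, exact permutation p = 0.0516 and 0.0389), the distance to the nearest cell (r = 0.728, rho = 0.830, p = 0.0437 and 0.0198) and the ratio of nucleus to cell area (r = -0.493, rho = -0.634, p = 0.197 and 0.110) had adjusted p = 0.0602, 0.0602 and 0.197 for r, and 0.0454, 0.0347 and 0.110 for rho, over the 7 measures. Over cells with at least 20 transcripts the rho of nucleus area had an adjusted p of 0.0639 by the exact permutation test. With each section left out in turn, rho passed for control probes and nucleus area 1 of 8 times and for cell area and the nearest distance 4 of 8 times. Without the 2 sections farthest from the median age, r was 0.969 for cells, -0.968 for transcripts, 0.910 for cell area, 0.955 for nucleus area, 0.892 for the nearest distance and -0.121 for the area ratio. For control probes it was -0.393, so that this relation rests on the day 21 sections. The 2 sections of an age overlap in outline, so that the 8 sections are not shown to be independent. With 1 mean per age (4 values), r was 0.979 for cells, -0.995 for transcripts, 0.899 for cell area and -0.921 for control probes, each with an adjusted p of 0.146 by the exact permutation test, so that no call was left. With 4 values the exact permutation test cannot go below p = 0.0417 for r.

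**Figure D4:**
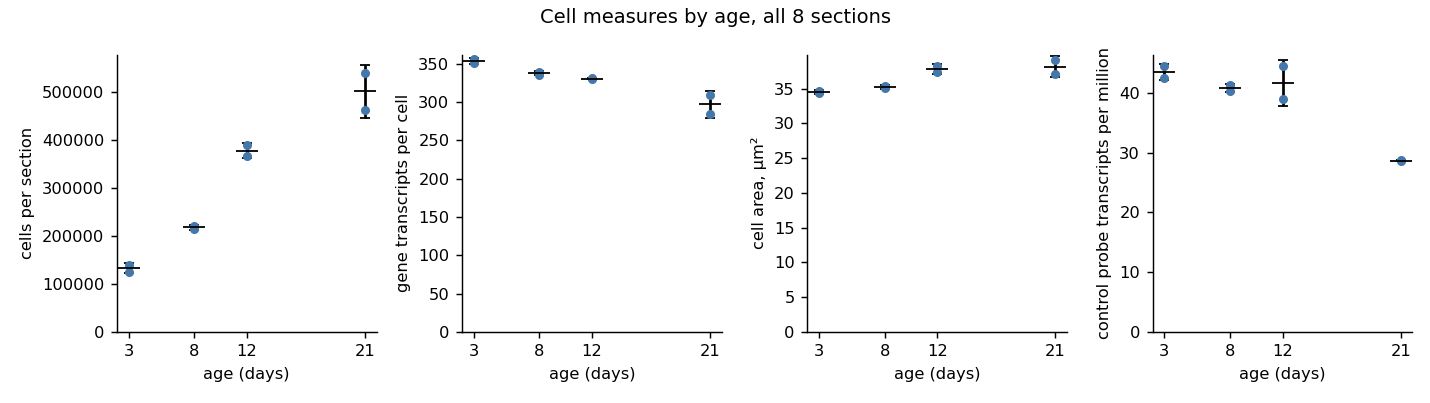
Cells per section, median gene transcripts per cell, median cell area (µm²) and control probe CPM against age in days; points are the 8 sections, and bars are the mean ± SD of 2. Cells per section went from 132676 at day 3 to 501978 at day 21.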

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

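All tests of explanations here, including the tissue pieces, the splits of them and the scales for genes that moved opposite ways, were chosen only after the results were seen, while the class-by-age and zone-by-age tests were planned.

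The day 8 against day 3 change differed between epithelial-like and stromal fibroblast-like cells for 373 of 480 genes by edgeR's quasi-likelihood test of the class-by-age term, and for 140 with pieces as blocks. Of the genes own to both classes, 23 moved opposite ways in them with the difference past the threshold. All 23 kept opposite signs with DESeq2's size factors and 21 with total counts as the scale, where Wwtr1 and Vangl2 did not. By the same limits under total counts 26 genes moved opposite ways, 19 of them among the 23. Anxa2 had a log2 fold change of -0.27 in the epithelium and 0.74 in the stroma, Egfr -0.16 and 0.61, Stra6 -0.13 and 0.62, and Rhou -0.15 and 1.69. Ihh had 1.72 and -0.56, Wif1 1.03 and -1.39, Foxa2 0.35 and -1.21, and Sox1 0.28 and -1.48, and these 4 had under 50 CPM at day 3 in both classes. With cells classed by marker score, epithelial Foxa2 turned to -0.36. Over pieces, 22 of the 23 kept opposite signs and 18 kept the difference past the threshold, but in only 2 did both changes pass as well. The near-to-far difference in the stroma differed between the ages for 289 genes, and for 81 with pieces as blocks.

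The first pattern is a fall of rarely read genes at day 8: in stromal fibroblast-like cells 77 of the 202 genes that fell had under 50 CPM at day 3. Misreading in general is argued against as the whole cause by the control probes, whose level per gene transcript in the day 3 pieces was 1.11 times that in day 8 pieces 1, 2, 3 and 5, where a ratio of 1.5 or more was needed, and by control codewords, at 58.7 and 61.1 CPM in the day 3 sections and 64.2 and 64.3 in those of day 8. Day 8 piece 4 had a control probe level of 50.1 CPM, against 36.9 to 41.3 in the other day 8 pieces. Within day 8 this goes with misreading as a part of the cause, but by less than the rarely read genes differ. The day 3 pieces overlapped both, from 39.1 CPM in piece 2 to nearly the level of day 8 piece 4 in piece 5. A background read in every cell type alike stays open as a candidate explanation, since the level of the 77 genes differed by a median of only 1.84 times between the highest and lowest of 4 classes, against 3.61 times for the other 125 genes that fell. Age stays open too and cannot be told apart from a difference between tissue pieces: day 8 piece 4 had 1.20 times the day 3 level and the other day 8 pieces 0.337 to 0.413 times, and 1 piece alone excludes nothing.

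The second pattern is that day 3 pieces 1 and 2 stand apart from the other day 3 pieces, with more cells of cluster 3. Pieces that belong to day 8 are argued against: over 199 stromal genes, pieces 1 and 2 lay at a median position of 0.430 on the way from day 3 (0) to day 8 (1), with quartiles of 0.160 and 0.683, where 0.75 or more was needed. An exchange of day 3 piece 2 with day 8 piece 4 is argued against by day 3 piece 2, which lay at 0.377 (quartiles 0.188 and 0.582, 278 genes), while day 8 piece 4, at 0.516 (quartiles -0.11 and 1.07), had too wide a spread to decide. Regional or individual differences between the pieces were not tested, since the labels give neither.

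With 5 pieces per age as replicates, 100 splits of the 10 pieces were drawn for each class, the real one included. As many genes as the real split were given by 1 of 100 splits for the whole section (58 genes, highest other 50), 1 for epithelial-like cells (133, highest other 1) and 1 for stromal fibroblast-like cells (146, highest other 122). For smooth muscle-like cells it was 2 of 100 (123, highest other 145) and for blood endothelial-like cells 2 of 100 (52, highest other 88). For each of the 5 counts this is under 0.05 of the splits, without adjustment over the 5. If the pieces can be exchanged, this argues against chance for each count taken alone. The splits cannot tell age from other differences between the pieces of the 2 ages, and whether pieces come from different animals is not known. For all but the epithelial-like cells the highest other split exchanges day 3 piece 2 with day 8 piece 4 and keeps 4 pieces of each age together. Other exchanges of 1 piece per age among those drawn gave at most 15 (whole section), 33 (stromal fibroblast-like), 99 (smooth muscle-like) and 39 genes (blood endothelial-like). Why this exchange gave more was not tested. Without day 3 pieces 1 and 2 and day 8 piece 4, the counts over pieces were 180 (whole section), 215 (epithelial-like), 278 (stromal fibroblast-like), 305 (smooth muscle-like) and 223 (blood endothelial-like).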

How the results depend on the processing

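Settings with tissue pieces, 1 mean per age, single clusters or genes under 50 CPM left out were chosen only after the results were seen. So were those of small against large groups with DESeq2's size factors, no filter or a replicate left out. Gene counts over sections stayed within 1.5 times, for the whole section and the 4 main classes, under DESeq2's size factors and Wald test, total counts, no filter, both cell minimums, finer clusters and the marker score. With a replicate left out they were 345 to 366 (whole section), 308 to 351 (epithelial-like), 389 to 415 (stromal fibroblast-like), 386 to 393 (smooth muscle-like) and 294 to 320 (blood endothelial-like). They were 346 to 371 for the class-by-age term, 360 to 382 near against far, 225 to 274 for its difference between ages and 236 to 351 for small groups. Without day 3 pieces 1 and 2 the sections gave 419, 386, 416, 419 and 373 for the whole section and the 4 classes. Counts of small classes moved more with a replicate left out: 179 to 261 (mesothelial-like), 136 to 246 (cluster 15) and 45 to 110 (cluster 18). A lone section left in an age is assumed to vary like the others. At resolution 0.5 no cluster was smooth muscle-like, so that no value exists there.

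Against a 1.5-fold change 92 genes passed for the whole section, 101 epithelial-like, 157 stromal fibroblast-like, 116 smooth muscle-like and 84 blood endothelial-like. With pieces as replicates the counts were 58, 133, 146, 123 and 52. Without day 3 pieces 1 and 2 they were 128, 169, 199, 148 and 109, and also without day 8 piece 4 they were 180, 215, 278, 305 and 223. Blood endothelial-like cells with endothelial neighbours gave 162 genes. Pieces as blocks gave 140 genes for the class-by-age term and 81 for zone by age. A test against a 1.5-fold change leaves out smaller changes by construction, and for the other counts the cause was not tested.

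With the replicate number as a block, 360, 364, 418, 403 and 360 genes passed, and cluster 18 went from 77 to 39. Numbers are not known to pair sections (correlation of same-numbered deviations -0.227), and the block uses up degrees of freedom. Of 13 gene lists, fry called 12 (whole section), 7 (epithelial-like), 12 (stromal fibroblast-like), 12 (smooth muscle-like) and 7 (blood endothelial-like). With the block it called 1, 1, 4, 0 and 0. Camera called 0 in each with an estimated correlation and 1 in each with a preset one: angiogenesis in epithelial-like cells (adjusted p = 0.0430) and the cell-cycle list in the others (0.0000827, 0.00000125, 0.0000440 and 0.00000108). With a replicate left out, fry called 0 (whole section), 0 (epithelial-like), 2 to 6 (stromal fibroblast-like), 0 to 6 (smooth muscle-like) and 0 to 4 (blood endothelial-like). Most list calls were thus lost with fewer sections, and the cause was not tested.

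With classes by marker score, the day 8 less day 3 distance to epithelium turned to 9.19 (stromal fibroblast-like), 19.1 (smooth muscle-like) and 5.11 µm (blood endothelial-like). The share of smooth muscle-like cells turned to 4.13 and of mesothelial-like cells to -3.07 percentage points, and epithelial Foxa2 to -0.36. Finer clusters gave 0.709 for the smooth muscle-like share. With a replicate left out the cluster 8 distance was -30.5 to 3.75 µm. Il1b was -0.41 without day 8 piece 1, Hoxa13 0.017 in smooth muscle-like cells with cluster 3, and zone-by-age Adh1 -0.16 with far cells at 100 to 200 µm. In endothelial cells with endothelial neighbours Fgf10 was -0.75, Gfra3 -0.079, Gli1 -0.10 and Esr1 -0.16. Over pieces without day 3 pieces 1 and 2, Wnt8a in cluster 3 was 1.48, and 0.16 also without day 8 piece 4. Esr1 there was 0.060 over pieces, 0.14 and 0.19 with those left out, and 0.015 over sections without day 3 pieces 1 and 2. Lcn2 in cluster 15 was 1.25 over sections and 0.95 over pieces without day 3 pieces 1 and 2, and 0.50 also without day 8 piece 4. The cause was not tested.

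For cell measures against age, without the 2 sections farthest from the median age r was 0.955 for nucleus area, 0.892 for the nearest-cell distance and -0.393 for control probes. The section mean gave 0.845 for nucleus area. With 1 section left out, r was 0.754 to 0.935 for cell area, which lost its call at 0.809, 0.796 and 0.754. It was 0.583 to 0.906 for nucleus area, which gained its call at 0.803 and 0.906, and 0.608 to 0.881 for the nearest distance, which gained it at 0.830 and 0.881. For control probes it was -0.981 to -0.836, and the call was lost at -0.836 without day 21 replicate 1. By Spearman's rho, with 1 of the 8 left out, the exact permutation test kept the calls of cells and transcripts 8 times, cell area and the nearest distance 4, and nucleus area and control probes 1. Nucleus area lost its rho call over cells with at least 20 transcripts (adjusted p = 0.0639). With 1 mean per age, r was 0.979 for cells, -0.995 for transcripts, 0.899 for cell area and -0.921 for control probes, and all 4 calls were lost. Fewer values raise the smallest possible p, and for the gains the cause was not tested. Genes under 50 CPM rest on few transcripts, which limits what can be said of them.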

Other observations

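The counts and p-values over tissue pieces were chosen only after the results were seen. The median number of genes per cell was 136 and 137 in the day 3 sections and 134 and 134 in the day 8 sections. Control codewords had 58.7 and 61.1 CPM, relative to gene transcripts, at day 3, 64.2 and 64.3 at day 8, 60.6 and 61.4 at day 12, and 49.1 and 55.3 at day 21.

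Mmrn1, a gene of lymphatic vessels, rose over the whole section by a log2 fold change of 1.45 ± 0.14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00045 over sections, 0.15 over pieces). In the stroma Tgfb3 (0.98 ± 0.02), Nog (1.04 ± 0.03), Vegfc (1.17 ± 0.03) and the semaphorin receptor gene Nrp2 (1.19 ± 0.03) rose, while Bmp5 (-1.58 ± 0.04) and the matrix gene Ltbp2 (-1.54 ± 0.04) fell, and each of these 6 passed over pieces. Nrp2, Bmp5, Ltbp2 and Hes1 are not among the stroma's own genes. Ltbp2 is among the leading genes of cluster 10, which counted as stromal and came mostly from day 3. It also leads the similar cluster 8, which was left out of the class and came mostly from day 8. The fall of Ltbp2 may therefore depend on this split, which the comparison over pieces shares. Of 12 Notch genes in the stroma 7 rose and 1 fell (8 adjusted over the list alone, 2 up and 1 down over pieces; fry adjusted p = 0.00379, which passed 1 of 4 times with a section left out; camera adjusted p = 0.802 with an estimated correlation), with Hes1 at 0.81 ± 0.02 and Notch3 at -0.54 ± 0.02.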
